A study of Homo sapiens with 2 samples.

How the data were processed

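H3K27ac ChIP-seq and input DNA sequencing were carried out on the T-ALL cell line LOUCY, 1 library each. Per the labels' protocols, chromatin was cross-linked with formaldehyde, sonicated and precipitated with an antibody against H3K27ac, and libraries were sequenced single-end without strand information. Per the submitters' processing notes, Bowtie2 and MACS2 were used with the hg19 build. The Bowtie2 version and alignment settings are not given in the sources used here.

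Peaks were called by the authors with MACS2 version 2.1.0.20140616 in broad mode, the ChIP library against the input library, per the file headers. Tags were 84 bp, the fragment length was set to 204 bp, the effective genome size to 2700000000, and 1 tag was kept per position. The filter dropped 13.2% of ChIP tags and 3.07% of input tags, and the larger library was scaled towards the smaller. Dropping repeated positions caps the height of the strongest peaks. The list was called on 1 library pair, with no pooling stated.

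The deposited fold enrichment is a ratio of ChIP pileup to the local control level, 1 value per broad peak. The deposited -log10 p-value and -log10 q-value are the caller's own values per peak. How the caller combined positions into 1 value per broad peak is not stated in the header. These are the authors' values and were used only to describe, rank or filter peaks; no p-value was computed across peaks, since peaks are not replicates. The deposited width equalled end minus start plus 1 in every row. The deposited pileup was below 0 in all 52203 rows and was not used, so large domains were ranked by fold times width, the alternative named in the design for that case.

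No hg19 genome sequence and no full hg19 gene annotation were used here. The gene table at hand was of GRCh38.p14, and it was used only to turn gene identifiers into symbols and gene types. Band names, stains and chromosome lengths came from the hg19 cytoband table in the R package circlize 0.4.16. Gene positions came from the small hg19 sample of UCSC known genes in the R package GenomicFeatures 1.54.1, with 44 genes and 147 transcripts on the standard chromosomes, of which 43 genes matched a symbol. A promoter was 1 kb either side of any start site, and a peak touching it by 1 bp or more counted. Statements on which gene families lie in a band are textbook background. Planned analyses that need a full annotation or sequence (peaks by genomic feature, promoters by chromosome, most of the gene lists, motifs in distal peaks) were not run.

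The items named followed a rule set before the data were examined. Without a full annotation the rule took peaks by coordinate: the 10 of highest fold, the 10 widest, the 15 highest domains and the 3 longest gaps. In the small gene set it took the 10 protein-coding genes of highest promoter fold and the members of the fixed lists, and the HOX genes as clusters. The other genes and bands named were chosen after their values were seen. Domains were made by joining peaks within 12500 bp and cutting the rank curve where its slope on the unit square reached 1. Peaks near start sites could not be left out as planned and were kept.

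The implied input level of a peak is the control level at which its fold, with 1 added to pileup and control, has its Poisson -log10 p. It was solved per peak, and 200 peaks with a level above 20, of which 191 had a fold below 3, were set aside for medians along chromosomes. Because fold and p may be combined over positions within a broad peak, the level is approximate. The single best step per chromosome was found with a rank cumulative sum and at least 50 peaks on either side. Intervals came from 1000 draws of blocks of 20 neighbouring peaks, which keep the position of the step fixed. As a check of the calculation, levels were simulated for 52203 peaks and solved back. At folds above 1.5, 100% were recovered within 5%. The same formula was used both ways, so this does not test whether it holds for broad peaks. A simulated log2 step of -0.50 among 1000 peaks was placed with a median error of 1 peak. Those peaks were drawn independently, while real levels varied along chromosomes. On chromosome 4 the step statistic was 12.4, against at most 4.07 in 100 shuffled orders. The error therefore need not hold for real steps.

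Alternatives were stricter thresholds on q and fold, merging of near peaks, other promoter windows and overlaps, another stitching distance and other ranking values. Shares carry 95% Wilson intervals, which cover counting error only. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.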

Results

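Acetylation of histone H3 at lysine 27 (H3K27ac), a mark of active promoters and enhancers, was mapped by chromatin immunoprecipitation and sequencing in LOUCY, an established human cell line from a T-cell acute lymphoblastic leukaemia (T-ALL) that is widely used as a model of the immature, early T-cell precursor form of the disease. The series held 1 H3K27ac library and 1 library of input DNA, the sheared chromatin before immunoprecipitation. The ChIP library had 62626946 aligned tags, of which 54357332 were kept by the peak caller, and the input library had 74212738, of which 71932640 were kept. There were no replicates, so all values describe these libraries, and no value across libraries was tested. The question was where in the genome of this line the mark was found, how strong and how wide it was there, and which regions carried the most of it.

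The mark was called in 52203 peaks on the 22 autosomes and chromosome X, which together covered 148.837 Mb or 4.90% of the genome. The median peak was 1670 bp wide (interquartile range 793 to 3319) and had a fold enrichment over input of 3.08 (interquartile range 2.42 to 5.70, highest 26.6). Weak peaks were the most numerous, while those of a fold from 6 to 10 covered the most sequence. The 25156 peaks with a fold below 3 made up 48.2% of all peaks, had a median width of 836 bp and held 18.3% of the covered sequence. The 9407 peaks with a fold from 6 to 10 made up 18.0% of peaks, had a median width of 3891 bp and held 36.3% of it. The 2718 peaks with a fold of 10 or more had a median width of 4761 bp. Across peaks, which are not independent replicates, width and fold rose together (Spearman's rho 0.741). Both values come from the same calls made against a threshold, so part of this relation may stem from the calling. A q cutoff of 0.05 stood in the caller's settings, yet the lowest -log10 q in the list was 1.01, and 51.0% of peaks lay below a -log10 q of 5. The number of peaks therefore depended on the threshold, as did the median width. At a -log10 q of at least 10 there were 19199 peaks, with a median width of 3743 bp.

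**Figure D1:**
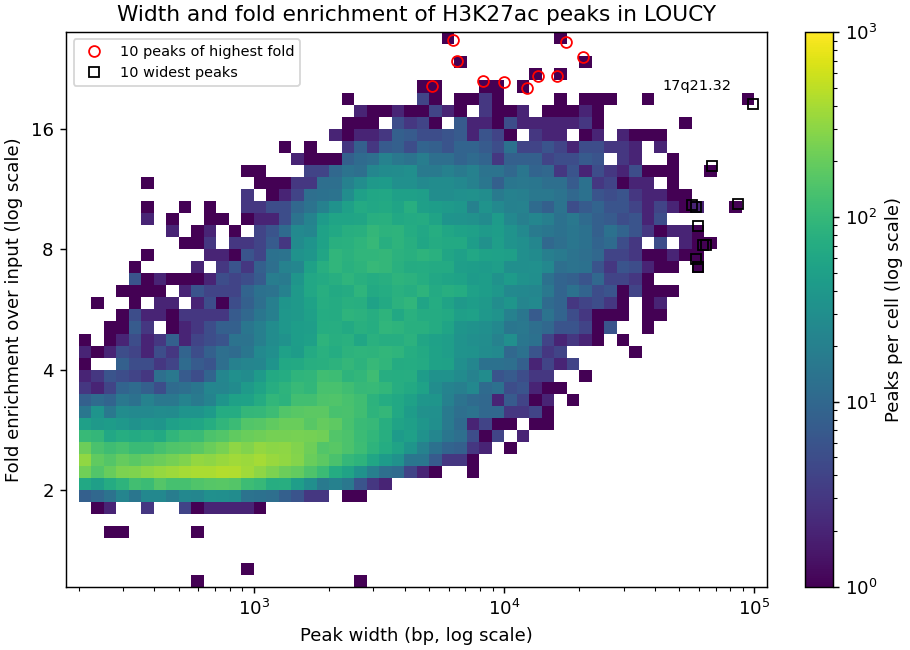
Number of H3K27ac peaks in LOUCY by peak width in bp (horizontal, log scale) and fold enrichment over input (vertical, log scale), with the colour of each cell on a log scale. Circles mark the 10 peaks of highest fold and squares the 10 widest peaks; the widest, in 17q21.32, reached 98820 bp at a fold of 18.4.

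The strongest peak lay in 11p15.5, at position 1907996 to 1914251 of chromosome 11 in hg19, with a fold of 26.6 over input. The next was in 7q34, the band of the T-cell receptor beta genes, at 142493940 to 142511557 of chromosome 7, with a fold of 26.4 and the highest -log10 p of the list, 269. Behind them came peaks in 17q22 (56404851 to 56425431, fold 24.2), 16p11.2 (30193397 to 30199847, fold 23.7), 19p13.2 (13203790 to 13220053, fold 21.6), 19q13.42 (55759329 to 55772978, fold 21.6) and 3p21.31 (50373062 to 50381319, fold 21.1). The remaining peaks among the first 10 were in 9q34.3 (139921470 to 139931458, fold 20.9), 8p23.1 (6690445 to 6695614, fold 20.5) and 5q31.1 (134360449 to 134372802, fold 20.3). The peak in 5q31.1 covered the whole of PITX1, a homeobox transcription factor gene of hindlimb and pituitary development.

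Peaks of 10000 bp or more numbered 2280, or 4.37% of all peaks, and held 25.6% of the covered sequence. Of these, 18 were 50000 bp or wider, and each of the 18 had a fold of at least 7.23. The widest peak of the list spanned 98820 bp of 17q21.32, from 46632431 to 46731250, and was also the peak ranked 29 by fold, at 18.4. The second was in 11q24.1 (122550675 to 122636642, 85968 bp, fold 10.4). The third was in 7p15.2 (27174299 to 27241865, 67567 bp, fold 12.9). The bands 3q27.3 (64141 bp, fold 8.19), 9q33.3 (62377 bp, fold 8.19), 1q32.1 (59516 bp, fold 9.17), 12q24.22 (58464 bp, fold 10.2) and 9q22.2 (56357 bp, fold 10.3) each held 1 of the 10 widest peaks. The band 21q22.12, which holds the haematopoietic transcription factor gene RUNX1, held a pair of them, at 36366813 to 36426572 (59760 bp, fold 7.23) and 36272480 to 36330706 (58227 bp, fold 7.56). The 522 widest and the 522 strongest peaks had 59 members in common, against 5.22 for independent lists. Width and fold come from the same calls, so independence is only a nominal reference.

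The HOX genes, homeobox genes that are active in blood stem cells and in subgroups of T-ALL, lie in 4 clusters in different bands. The bands of the HOXB cluster (17q21.32) and the HOXA cluster (7p15.2) held the widest and the third-widest peak of the genome, and in both bands that peak was also the strongest of the band. The band of the HOXC cluster, 12q13.13, had a widest peak of 36548 bp (51754261 to 51790808) with a fold of 5.97. Its strongest peak lay elsewhere in the band (54800894 to 54816004, 15111 bp) and ranked 292 by fold. The band of the HOXD cluster, 2q31.1, had a widest peak of 18476 bp (173133405 to 173151880), which ranked 621 by width. Its strongest peak (176960331 to 176963018) was 2688 bp wide with a fold of 18.2, rank 31 by fold. These bands also hold other genes, and the peaks were not assigned to genes within them. The values therefore compare bands, and the peaks named need not lie in the HOX clusters.

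In 2 of the 3 bands of T-cell receptor genes, the strongest peak had a higher fold than any peak in the bands of the immunoglobulin genes. The strongest peak of 7q34 (receptor beta) ranked 2 by fold, and that of 14q11.2 (receptor alpha and delta) ranked 17, with a fold of 19.0 over 36226 bp at 22925355 to 22961580. The strongest peak of 7p14.1 (receptor gamma), at 37959329 to 37961987, had a fold of 11.1 and ranked 1582. Among the immunoglobulin bands, the strongest peak of 22q11.22 (lambda), at 22592929 to 22607137, had a fold of 15.7, rank 128. That of 2p11.2 (kappa), at 85761423 to 85768539, had a fold of 14.6, rank 215. That of 14q32.33 (heavy chain), at 106548705 to 106577181, had a fold of 13.9, rank 338. The receptor and immunoglobulin bands were picked after the peaks had been seen, and each holds other genes too. The values compare the strongest peak per band, wherever in the band it lay. No peak was placed in a receptor or immunoglobulin gene.

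Peaks were then stitched within 12500 bp and the resulting 25510 regions ranked by the sum of fold times width, to find the regions with the most H3K27ac. The slope rule set apart 1421 large domains, 5.57% of regions, which held 44.1% of the summed value. Their median span was 54.6 kb against 2.92 kb for the other regions, and they held a median of 7 peaks. The first-ranked domain was in 17q21.32 (46616925 to 46731250, 114 kb, 3 peaks), though it ranked 38 by summed width alone. The second was in 6q23.3, the band of the MYB proto-oncogene (135394153 to 135670464, 276 kb, 26 peaks, highest fold 19.7). It lay in the part of 6q with a low input level, which enters the fold, and it ranked 12 when implied pileup replaced fold, an alternative chosen after the data had been seen. Next came domains in 20q11.21 (31092008 to 31367842, 276 kb), 11q24.1 (122499962 to 122729478, 230 kb), 6p23 (14207492 to 14492612, 285 kb) and 6p22.2, the band of a large histone gene cluster (26152600 to 26342966, 190 kb). The domain in 14q24.1 (69005776 to 69332756) had the longest span of all large domains, 327 kb, with 42 peaks. The domains ranked 8 to 15 lay in 9q22.2, 3q26.32 (313 kb, 40 peaks), 14q11.2 (highest fold 19.0), 21q22.12 (174 kb), 8q24.22, 19p13.12, 12p13.31 (highest fold 18.8) and 1q32.1. Peaks near promoters were kept in this ranking, so the domains are not enhancers alone. The set also depended on the threshold. At a -log10 q of at least 10 there were 814 large domains, and 6 of the first 15 were among the first 15 again.

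**Figure D2:**
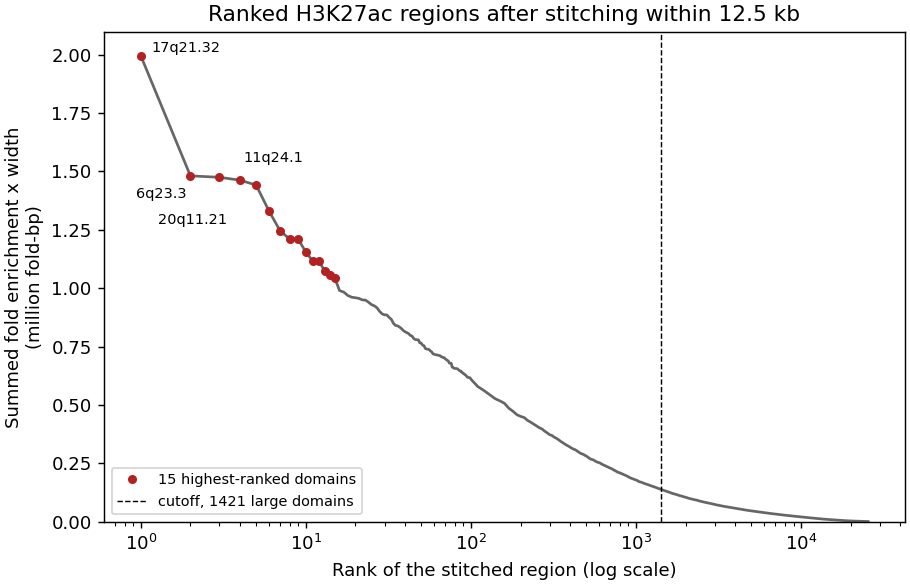
Stitched H3K27ac regions in LOUCY by rank (horizontal, log scale) and summed fold enrichment times width (vertical, fold times bp, scaled down by 1000000). Points mark the 15 highest domains, led by 17q21.32, and the dashed line the rank below which regions were not counted among the 1421 large domains.

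Peak density differed across chromosomes. Chromosomes 19 (30.1 peaks per Mb), 17 (29.3) and 22 (23.3) were the densest, and chromosomes X (9.72), 4 (12.4) and 13 (12.7) the sparsest. Chromosome 19 also had the highest median fold, 5.26, against 2.82 on chromosomes 4 and 13. Fold is a ratio to the local input level, so part of this contrast may lie in the input. The median implied input level was 5.84 on chromosome 19, 7.02 on chromosome 4 and 7.41 on chromosome 13. Chromosome X, with the lowest median level (4.69), had a median fold of 3.45. Giemsa-negative bands had 23.3 peaks per Mb and the lightest of the stained classes 24.7, while the darkest-staining bands had 8.65. The longest stretch without a peak outside centromeres and heterochromatin was 7.16 Mb on chromosome X (86773084 to 93928641, from Xq21.31 to Xq21.33). The next were 6.92 Mb on chromosome 4 (27005848 to 33923023) and 4.87 Mb on chromosome 13 (53277934 to 58144471). Chromosome lengths include assembly gaps, which lowers the density of chromosomes with long unsequenced parts.

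At promoters, the mark was found at 26 of 38 protein-coding genes of a small hg19 gene set, 68.4% (95% Wilson interval 52.5 to 80.9), against 8.56% of 10000 random positions. A gene counted if any of its start sites was near a peak, while each random position had a single window. With only the start site furthest 5' of each gene, the share was 60.5%. The interval covers counting error only, and how the set was drawn is not given in the sources used here, so the share need not hold for all genes. Folds at the 26 promoters ran from 2.93 to 20.3, with a median of 7.01 and a median peak width of 3184.5 bp. PITX1 (134363424 to 134369964 of chromosome 5, minus strand) was first with a fold of 20.3, rank 10 of all peaks. ETV6, an ETS-family repressor often rearranged in leukaemia, was second with a fold of 12.2 at its promoter. The 2 transcripts listed for it in the set together spanned 465474 bp (11802788 to 12268261 of chromosome 12). In that span, 21 peaks covered 79191 bp. Whether the whole span belongs to ETV6 was not examined, so these peaks need not all lie in the gene. Next were SKA3, a kinetochore component (fold 10.5), R3HDM1 (9.81), AMPD3, an AMP deaminase (9.21), and MLC1, best known from astrocytes (9.14). DXO, an RNA decapping enzyme (8.96), ZNF107, a zinc finger gene (8.83), PHF8, a histone demethylase (7.89), and IQCC (7.20) completed the first 10.

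Further promoter folds, of genes picked after their values were seen, were those of the mitochondrial tRNA synthetase gene SARS2 (7.20), the splicing factor gene PRPF39 (6.89), the replication timing factor gene RIF1 (6.62) and the splicing kinase gene SRPK1 (6.32). The lowest folds were those of PFKFB2 (3.16) and BCAS1 (2.93). The 12 genes with no promoter peak were the olfactory receptors OR12D2 and OR2K2, the hair keratin KRT85, the egg coat protein ZP3, the squamous serpin SERPINB4, the liver enzyme UROC1, the myeloid genes S100A9 and TLR2, IDO2, LRRC52, CLCN4 and TBC1D12. The nearest peak to a start site of SERPINB4 was 220 kb away, and that of ZP3 was 3.35 kb away. At UROC1, 3 peaks covered 51.5% of the gene outside its promoter. Of the 292 genes on the 18 lists fixed before the data were examined, only ETV6 (immature T-ALL and progenitor regulators; promoter peak) and S100A9 (myeloid markers; no promoter peak) were in this set.

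**Figure D3:**
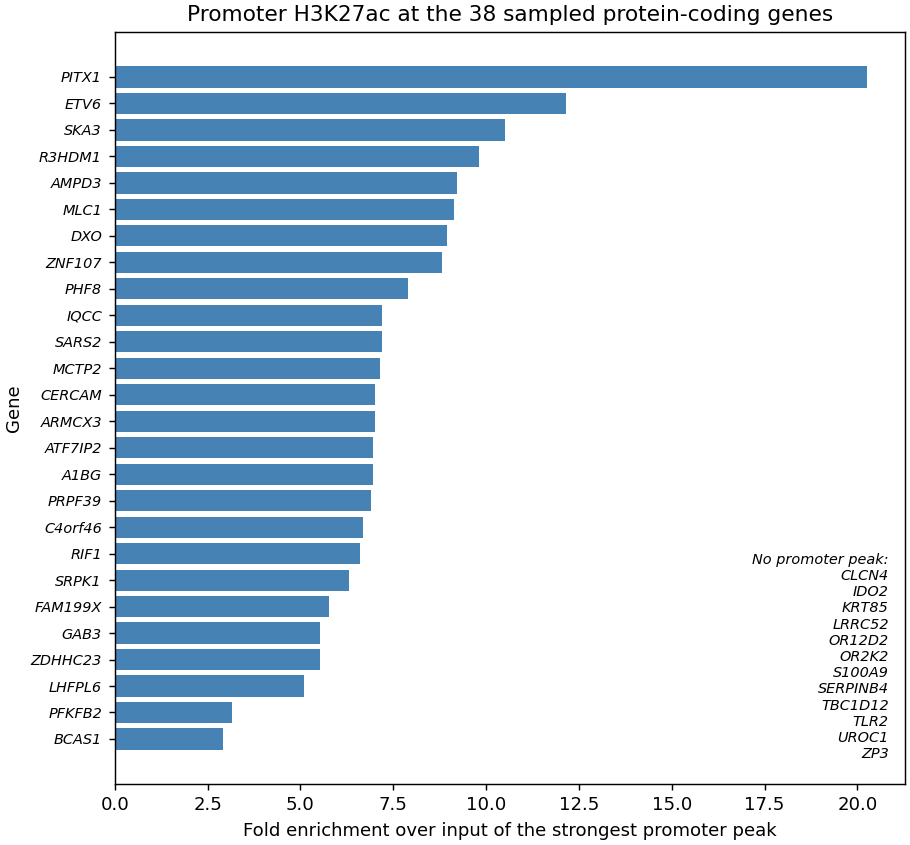
Fold enrichment over input of the strongest H3K27ac peak within 1 kb of a start site (horizontal, linear from 0) for the protein-coding genes of the hg19 gene set, 1 bar per gene and 1 library. PITX1 reached 20.3, and the 12 genes listed at the lower right had no promoter peak.

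The level of the input at each peak, worked out from the fold and p-value of the peak, also differed between regions. Its median over all peaks was 6.34, and its lowest value, 4.11, equalled the background of 4.11 that the caller sets as a floor. Chromosome X was low throughout, with a median of 4.69 over 1510 peaks against 6.41 on the autosomes. On chromosome 6 the best single step lay between positions 109123928 and 109124954, in 6q21. The median level dropped there from 6.80 to 4.67 (log2 difference -0.54, 95% block bootstrap interval -0.58 to -0.52). On chromosome 5 the best single step lay between 96520247 and 98107018, from 6.88 to 4.95 (-0.48, interval -0.54 to -0.40). No interval was worked out for the position of either step. These steps were the most marked of the 23 chromosomes by a rank statistic. The best steps of other chromosomes reached log2 differences of -0.37 (18q23), 0.37 (4p16.1), -0.36 (9q33.3) and 0.25 (1p32.2 and 16p12.3), so smaller steps were common. On chromosome 16 the level was 4.74 before position 17499230 and 5.63 after it. The measure was chosen after the data had been seen, and it cannot fall below the floor.

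**Figure D4:**
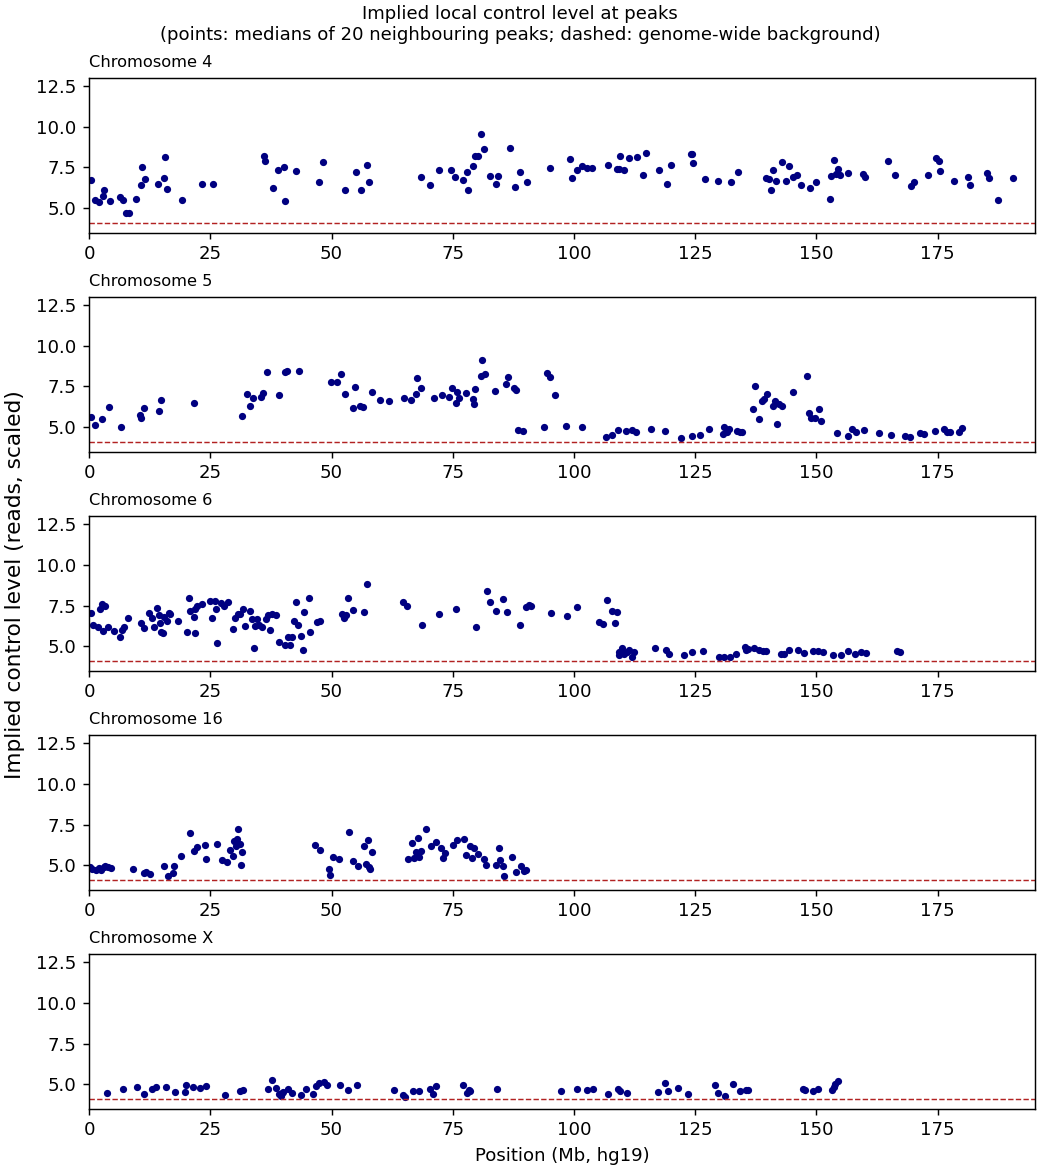
Implied input level at H3K27ac peaks (vertical, scaled reads) along chromosomes 4, 5, 6, 16 and X (horizontal, Mb of hg19), each point the median of up to 20 neighbouring peaks and the dashed line the caller's background of 4.11. Chromosome X lies near the dashed line over its whole length, and chromosome 6 falls from 6.80 to 4.67 in 6q21.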

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

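The alternatives that used a -log10 q of at least 10 for the median width, set aside peaks with a high implied input level, ranked domains by implied pileup or left out weak peaks, and those on the steps of chromosomes 5 and 6, were chosen after seeing the data. The number of peaks fell from 52203 to 25589 at a -log10 q of at least 5, to 19199 at 10 or more and to 19529 at a fold of at least 4, because the weak peaks were removed. At a -log10 q of at least 10 the median width rose from 1670 to 3743 bp, since the peaks removed were mainly narrow. Weak peaks were narrow, with a median of 836 bp at a fold below 3 against 4761 bp at 10 or more. The number of large domains fell from 1421 to 814 at a -log10 q of at least 10, and the cause of this fall was not tested. The covered share of the genome went from 4.90% to 3.41% under that threshold on q. Merging within 500 bp moved nothing, since the smallest gap between peaks was 817 bp. The promoter share stayed between 60.5% and 68.4% over the 5 alternatives, inside its interval. The large domains numbered 1414 with stitching within 5 kb, 1564 when ranked by width, 1503 by implied pileup and 1020 without peaks of fold below 3. Of the first 15 domains, 6 were among the first 15 again at a -log10 q of at least 10, 8 without peaks of fold below 3, 9 with stitching within 5 kb, 10 by width and 13 by implied pileup. The domain in 17q21.32 was first in 4 of 5 alternatives and ranked 38 by width alone, and that in 6q23.3 went from rank 2 to 12 by implied pileup. The steps on chromosomes 6 and 5 kept their sign under all 4 alternatives each, although all 4 values on chromosome 6 and 1 on chromosome 5 lay outside the interval of the main value. Not run were the alternatives for peaks at promoters, gene lists and motifs, which need a full hg19 annotation or sequence, and leaving out peaks near start sites. No paired analysis was possible because there was 1 library per group. At 1 library each, differences between neighbouring ranks have no replicate check.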

Other observations

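All tests in this part were chosen after the patterns had been seen, and those on the input level were revised more than once after earlier results. The revisions set aside the 20 peaks nearest each step (log2 differences -0.68 on chromosome 6 and -0.53 on chromosome 5), which the choice of the step favours, set the peaks beside a step against other positions, and replaced the smallest drop in a single Giemsa class by the mean drop within classes. Among the 24 windows of 5 Mb on chromosome X with at least 20 peaks, the median implied input level ran from 4.37 to 4.97. Of 527 autosomal windows, 29 were as low as the highest of these, 12 of them on chromosome 6, 11 on chromosome 5, 4 on chromosome 16 and 1 each on chromosomes 10 and 17. On 5q the low level was interrupted. It was 4.74 from 98.1 to 134.7 Mb (400 peaks), 6.46 from there to 151.4 Mb (369 peaks) and 4.69 from 153.4 Mb to the end (347 peaks). The change in 5q31.1, between 134685365 and 134690442, lay 313 kb from the PITX1 peak, the strongest promoter peak of the gene set and rank 10 of all peaks. By position that peak belonged to the low part. Its own level was 5.60, above the upper quartile of that part (5.19) and within the interquartile range of the inner segment (5.16 to 7.85). Those quartiles cover peaks of all folds, however. Among the 10 peaks of highest fold, levels ran up to 8.64, in 7q34, and 5.60 was the lowest. The quartiles therefore do not set the PITX1 peak apart from the low part. No test linked the position of the change in 5q31.1 to the acetylation of PITX1.

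A hypothesis for the low input level of distal 6q is that the sequenced cells may have held fewer copies of that segment. Its sharpness did not decide this: the 21st to 40th peaks on either side differed by a log2 of -0.47, but 5.47% of 43543 positions on other autosomes differed as much in either direction. The mean drop within Giemsa classes was -0.54 (95% interval -0.58 to -0.49), as large as the whole step, so the mix of classes did not account for it. Base composition itself stays open. Over the whole genome, class medians ran only from 6.16 (Giemsa-negative) to 6.87 (darkest), so averaging within classes could hardly have shrunk such a drop. Reads missing from the input alone stay open. The median fold rose by a log2 of 0.090 beyond the step, from 2.97 to 3.16. However, the peaks were called against that same input, and the 5th percentile of fold moved with it from 2.13 to 2.21. The rise therefore decides nothing. A cause that lowers both libraries alike, such as poor alignment, was not tested, and no karyotype was used here.

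For 5q the same hypothesis was weighed in the same way. The 21st to 40th peaks on either side of the step differed by -0.73, as large a difference as 0.374% of the positions on other autosomes showed, although the place of the step was chosen on the same values. Beyond the step, inner segment included, the whole drop was -0.48. The mean drop within Giemsa classes was -0.43 (95% interval -0.52 to -0.33). The mix of classes thus accounted for little of the drop, while base composition stays open, as for 6q. Single classes ran from -0.62 to -0.28, apart from -0.03 in a class whose 87 peaks all lay in the inner segment. The median fold rose by a log2 of 0.25 over the whole region beyond the step. It was 2.87 before the step, 3.25 in the first low part, 3.05 in the inner segment and 4.01 in the last part. Parts of like input level thus differed in fold, and reads missing from the input alone stay open for the reason given for 6q. On chromosome X the mean drop from the autosomes within Giemsa classes was -0.45 (95% interval -0.48 to -0.43). The mix of classes did not account for the low level of X either, and base composition stays open there too. The number of X copies was not analysed here.

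Nearly as many peaks were weak as not, and flanks of strong peaks could be 1 source of them. Of the 25156 peaks with a fold below 3, 33.6% lay within 12500 bp of a peak with a fold of 6 or more, against at most 13.7% in 100 random placements within chromosomes. Within that distance, the share is too low for flanks of those strong peaks to account for most weak peaks. It is too high for calls scattered at random. Flanks of the 14922 peaks with a fold from 3 to 6 were not counted, so the share of all flanks stays unknown. Of the weak peaks, 79.0% lay within 100 kb of a peak with a fold of 6 or more. No random placement was set beside that share, so it says nothing on clustering. Clustering of weak enhancers near active genes would give an excess within 12500 bp similar to that seen, and was not separated from flanks. No biological explanation was tested.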
